A study of Mus musculus with 4 samples.

How the data were processed

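RNA from 4 cultures of fetal liver progenitors was hybridized to Illumina MouseRef-8 arrays, 1 array per group, with biotin-labeled cRNA. Per the labels, cells carrying c-Kit without Ter119 were isolated with magnetic beads from C57BL/6J embryos at day 13.5, expanded for 24 hours, infected with retrovirus and kept for 48 hours more. They were then grown for 12 days with 10 ng/ml FLT3 ligand, 20 ng/ml interleukin 7 and 100 ng/ml stem cell factor. The labels do not say how many embryos made up a culture.

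The values are RMA-normalized log2 levels that the authors made in ArrayStar, per the file headers and the submitters' processing notes. RMA corrects the background and makes the distributions of the arrays alike, so a shift of all genes on an array cannot be seen in these values. The table holds 1 value for each of 18113 gene names, and how several probes of a gene were combined is not given in the sources used here. Per the file headers, the authors also deposited a fold ratio for each of 5 comparisons of arrays. These equaled 2 raised to the difference of the log2 levels within 1e-05 on the log2 scale, with the second named condition over the first. The authors' workbook held the same log2 levels as the value table, with a largest difference of 0. The remaining 8 columns, of non-normalized signals and detection p-values, have names that match no sample's labels, so they were not used.

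Before the data were examined, the plan was to normalize the raw signals with a normexp background, to use detection p-values as the floor and to measure the spread between different probes of a gene. None of these could be done from the values used. They were replaced, after the distribution of levels had been seen, by the authors' RMA levels, a floor of 6 on the log2 scale and a level-matched spread. The floor lies to the right of the trough between the low and the high mode of levels. Values below it were raised to it, and a gene entered a comparison if at least 1 of its 2 arrays lay at or above the floor. Where 1 array lay below it, the fold is given as a lower bound. The spread of a gene is 1.4826 times the median absolute deviation of the log2 differences among it and the 250 genes next to it in mean level on either side. For each comparison, 100 simulated pairs of arrays were drawn from that spread alone, and genes past 2-fold were counted.

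The 5 comparisons were fixed before the data were examined, each the log2 difference of 2 arrays, together with the difference between the ETV6-RUNX1 effects of the genotypes and the correlations of effects across genes. With 1 array per group no comparison of 2 groups could be tested, and no p-value is given. An additive model of genotype and virus would leave 1 residual degree of freedom among the 4 arrays. It takes both effects as equal in both backgrounds, was not planned and was not fit. Fixed as well were 28 gene lists. A list's median over its measured genes (at least 3) was set against 10000 random lists of the same size matched on deciles of mean level. That percentile describes these arrays only, and genes of a list are not independent of each other.

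The genes named were chosen by a rule fixed beforehand. For each comparison of 1 factor they are the 8 largest differences of at least 2-fold each way among genes above the floor on both arrays, and up to 3 bounds each way. For the other comparisons they are the 6 largest each way. From each list up to 4 members past 2-fold were taken, and members that show its spread. Btg1, Bcl6, Etv6, Runx1, sex-linked and housekeeping genes were always included. Genes known only by clone, accession or locus names were counted and not named, and the kinds of such names were widened slightly after the data were seen. Some genes that the rule selects are not reported here. Gene names come from the array table. Of them 14304 matched a symbol and 2643 a synonym in a RefSeq table of assembly GRCm38.p6, and 1166 kept the name of the file. No genome build is given for the arrays, so no coordinates are printed.

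The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated arrays of 18113 genes. In the simulated comparison of ETV6-RUNX1 in wild type, 100% of genes changed by 4-fold and 4% of those changed by 1.5-fold were called at 2-fold. In that of ETV6-RUNX1 in the knockout, the shares were 100% and 12%. The changed genes were drawn only from those with a mean level at least 4-fold above the floor. These shares therefore do not cover genes near it. The alternatives tried were scaling to an equal 75th percentile and restriction to genes above the floor on all 4 arrays, both planned, and floors of 5 and 7, no floor and a requirement of 3 times the spread, added after the data were seen.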

Results

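Gene expression was measured in cultured mouse fetal liver hematopoietic progenitors that differed in 2 factors, the Btg1 gene and the leukemia fusion ETV6-RUNX1. BTG1 is an antiproliferative co-regulator that is often deleted in childhood B-cell precursor leukemia, and ETV6-RUNX1 joins 2 transcription factors in the most common translocation of that disease. Progenitors carrying c-Kit and lacking the erythroid marker Ter119 came from wild-type or Btg1 knockout C57BL/6J embryos at day 13.5. They were transduced with a control retrovirus or with one expressing ETV6-RUNX1, and grown for 12 days with FLT3 ligand, interleukin 7 and stem cell factor. The 4 groups were wild type with control virus, wild type with ETV6-RUNX1, Btg1 knockout with control virus and Btg1 knockout with ETV6-RUNX1. Each group had 1 array, so no comparison of 2 groups could be tested, and no difference below has a replicate check. The series title asks whether BTG1 loss promotes transformation by ETV6-RUNX1 through higher BCL6.

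The arrays gave 1 log2 value for each of 18113 genes, normalized together by the authors. Between 5869 and 5900 genes per array lay at or above a level of 6, used here as the floor under which a value gives only a bound. Over genes at or above the floor on all 4 arrays, pairs of arrays correlated at Pearson r of 0.971 to 0.991. The array of Btg1 knockout cells with ETV6-RUNX1 stood apart. Over the 1535 genes with a mean level of at least 10, the robust standard deviation of the log2 differences was 0.120 between both control arrays and 0.135 between both wild-type arrays. It was 0.2402 to 0.296 in the comparisons that used the knockout array with ETV6-RUNX1. Differences are given as log2 differences, and "spread" beside a gene means the robust standard deviation among the gene and the 250 next to it in level on either side, between the same pair of arrays. That spread includes real differences among those genes and leaves out the variation between independent cultures. Differences called largest are so among genes at or above the floor on both arrays that the array table does not list by a clone or locus name, and bounds are given separately.

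Btg1 itself was lower in both knockout cultures, as their labels say. Its level was 11.87 in wild type with control virus and 11.97 in wild type with ETV6-RUNX1. In the knockout it was 9.02 with control virus and 9.97 with ETV6-RUNX1. The knockout value was 7.21-fold lower without the fusion and 4.01-fold lower with it, and both knockout values stayed well above the floor. Bcl6, a transcriptional repressor that protects pre-B cells and germinal center B cells, had its highest level where both lesions were present. Its levels were 6.75 and 7.30 in wild type without and with ETV6-RUNX1, and 6.33 and 8.86 in the knockout. ETV6-RUNX1 thus went with 5.76-fold higher Bcl6 in the knockout (log2 difference 2.53, spread 0.43) and with 1.47-fold higher Bcl6 in wild type (0.55, spread 0.32). The difference between these 2 effects was 1.97, with a spread of 0.52. Part of it lies in the knockout control, where Bcl6 stood close to the floor and differed by -0.42 from the wild-type control. With a floor of 7 the ETV6-RUNX1 difference in the knockout was 1.86. Mouse Etv6 lay below the floor on all 4 arrays, and Runx1 stood between 7.82 and 8.20, so the arrays gave no readout of the fusion transcript.

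**Figure D1:**
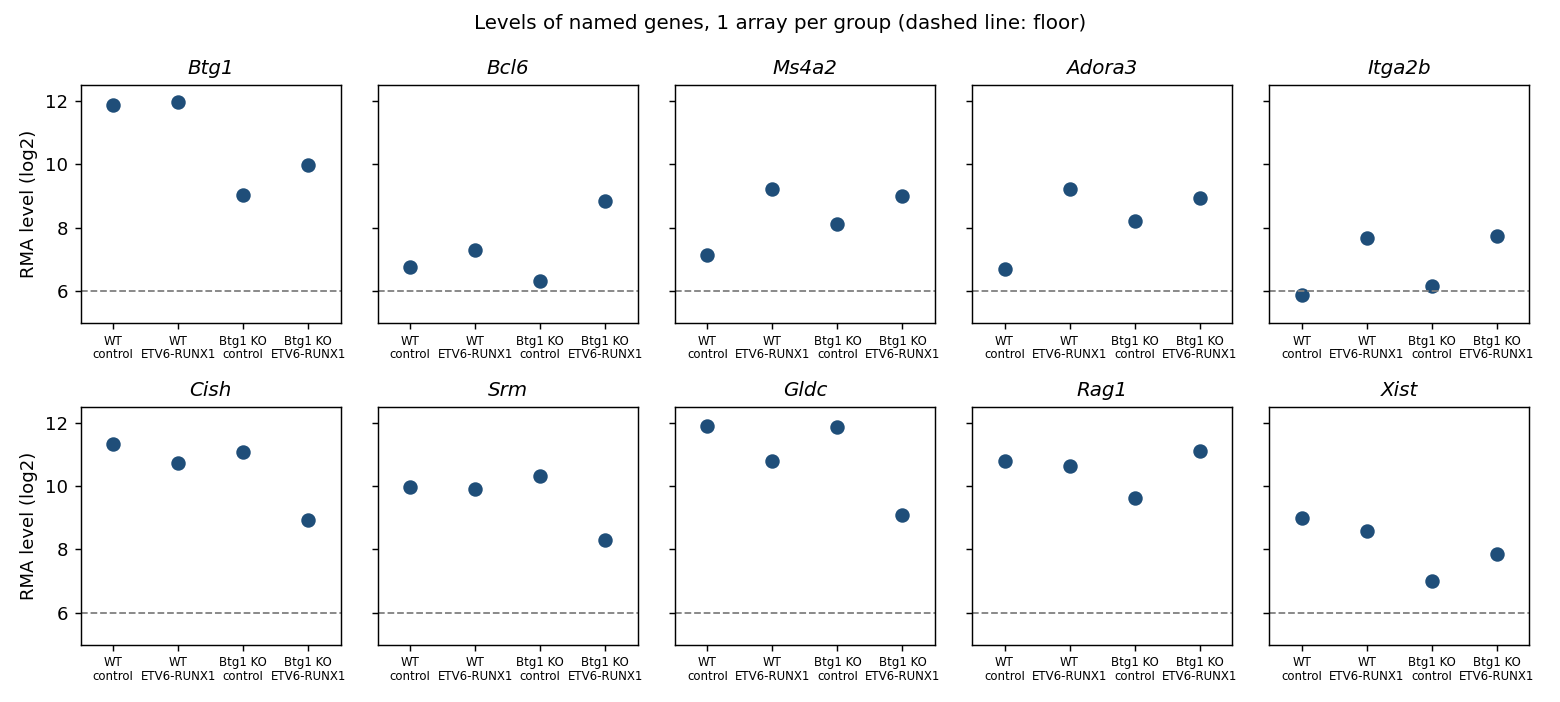
RMA level (log2, vertical axis) of 10 genes on the 4 arrays, 1 point per array with no replicates, and a dashed line at the floor of 6. Bcl6 reaches 8.86 in the knockout with ETV6-RUNX1 against 6.33 to 7.30 elsewhere, and Srm and Cish have their lowest levels there, at 8.30 and 8.94.

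ETV6-RUNX1 in wild-type cells was compared with the control virus to describe what the fusion does when Btg1 is intact. Genes of mast cells and basophils were higher with the fusion: all 11 measured members lay above 0, 10 of them by at least 2-fold, and the list's median of 1.40 exceeded those of all 10000 random lists of like level. Ms4a2, the beta chain of the high-affinity IgE receptor, differed by 2.09, the tryptase Tpsab1 by 1.83, and Slc18a2, the vesicular monoamine transporter, by at least 4.86-fold. The mast cell protease genes Cpa3 and Mcpt4 already stood at 13.63 and 13.01 in the wild-type control. Other genes with large differences were the adenosine receptor gene Adora3 (2.51, spread 0.26), the gene the file names MGL1 (2.22), Cd200r3 (2.15), the chemokine gene Ccl2 (2.09), Meis2 (2.07), the tetraspanin gene Cd63 (2.04) and Neo1 (2.02). C2, Pmp22 and Cd59a were below the floor without the fusion and at least 5.90-fold, 5.69-fold and 5.04-fold higher with it.

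Megakaryocyte genes were higher as well where measured, with 5 of 5 measured members above 0, 4 of them by at least 2-fold, and a median of 1.13 at the 99.99th percentile of random lists. The array held 14 genes of this list, and the others lay below the floor on both arrays. Itga2b, the platelet integrin alpha chain, was at least 3.19-fold higher, Cd9 differed by 1.60 and the transcription factor gene Nfe2 by 1.08. Of 7 measured stem and early progenitor genes, out of 22 on the array, 6 were above 0 with a median of 0.82, above all random lists. Among them Gata2 differed by 1.505, and Cd34 and Tal1 were at least 3.70-fold and 3.40-fold higher, whereas Eng differed by -0.62. All 7 measured granulocyte and monocyte genes, out of 32 on the array, were above 0 (median 0.70, percentile 99.98), with the Fc receptor gene Fcgr3 at 1.78 as the 1 member past 2-fold. Most genes of these lists were thus not measured, and the values do not tell which cells expressed the measured ones. Of the immediate early genes, 5 of 9 were above 0 (median 0.53), led by Ier3 at 1.45 and Fos at 1.27. Among genes of cell cycle control, cyclin D1 (Ccnd1) differed by 1.97 and the INK4a/ARF gene Cdkn2a by -1.14.

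Fewer genes were lower with the fusion in wild type. The largest such differences were Clic6 (-1.64), Apbb1 (-1.55), the nuclease gene Dnase1l3 (-1.55), Aph1b (-1.52), the lymphocyte receptor gene Ly9 (-1.31), Celsr1 (-1.28) and Smtnl2 (-1.21). The chemokine receptor gene Cxcr5 and Tenm4 were lower by at least 2.62-fold and 2.04-fold. B-cell progenitor genes had a median of -0.14 (14 of 20 below 0, percentile 0.54), STAT5 target genes of -0.34 (5 of 9 below 0, percentile 0.06) and interferon response genes of -0.33 (6 of 8 below 0, percentile 0.23). All 5 measured dendritic cell and MHC class II genes lay below 0, with a median of -0.34. MYC and ribosome biogenesis genes had a median of -0.05, at the 23.8th percentile. Overall 115 genes were at least 2-fold higher and 22 at least 2-fold lower among 6123 compared, and 14 were at least 4-fold higher. In 35 of these 137 genes 1 of the arrays lay below the floor. Simulated arrays without any difference beyond the spread gave a median of 20 such genes, and the count moved to 75 with a floor of 7 and to 241 with a floor of 5.

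**Figure D2:**
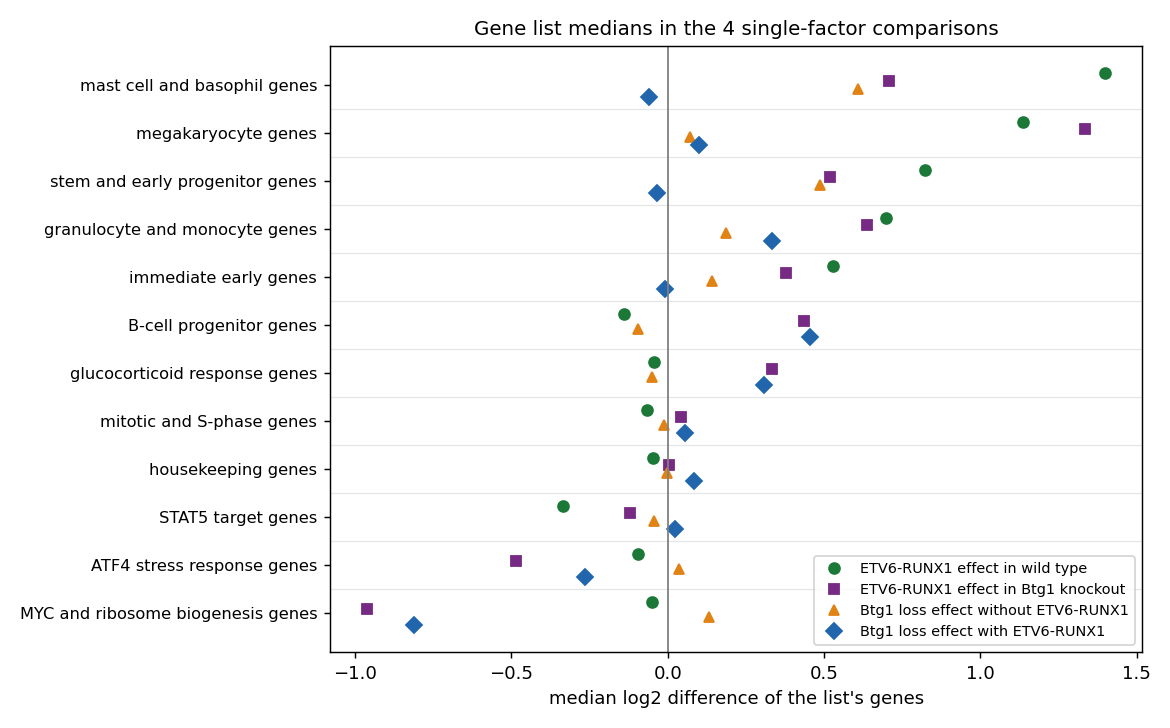
Median log2 difference (horizontal axis) of the measured genes of 12 lists in the 4 comparisons that vary 1 factor, 1 symbol per comparison and 1 array per group. Mast cell and basophil genes reach 1.40 with ETV6-RUNX1 in wild type, and MYC and ribosome biogenesis genes -0.96 with ETV6-RUNX1 in the knockout.

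In Btg1 knockout cells, MYC and ribosome biogenesis genes were lower with ETV6-RUNX1 throughout: 14 of 14 measured members lay below 0, 7 by at least 2-fold, and the median of -0.96 was below those of all 10000 random lists. Srm, the spermidine synthase gene, differed by -2.005 (spread 0.33), the nucleolar GTPase gene Gnl3 by -1.69, Rrp12 by -1.57 and the snoRNP gene Nop56 by -1.11. ATF4 stress response genes, which include enzymes of serine and one-carbon metabolism, had a median of -0.49 (12 of 15 below 0, below all random lists), with Shmt2 at -1.19 as the member past 2-fold. Besides Srm, the largest lower differences were Gldc, the mitochondrial glycine decarboxylase gene (-2.78, 6.88-fold), the connexin 43 gene Gja1 (-2.45), the invariant chain gene Cd74 (-2.38), Dctd (-2.15), Ifrd2 (-2.15), Cish, a feedback inhibitor induced by STAT5 (-2.13), and Sema4a (-1.95). The STAT5 list as a whole had a median of -0.12 (5 of 9 below 0), with Bcl2, an inhibitor of apoptosis, at -1.92 and cyclin D2 (Ccnd2) at -1.01. Serpina3g, Cacna1h and Slc25a33 were lower by at least 3.79-fold, 3.74-fold and 3.36-fold.

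B-cell progenitor genes lay above 0 in 21 of 21 measured members, with a median of 0.43 above all random lists, and 2 passed 2-fold. These were Rag1, a subunit of the V(D)J recombinase, at 1.47 (spread 0.35), and Dntt, the terminal transferase gene, at least 2.07-fold higher. Mast cell and basophil genes were above 0 in 11 of 11 members, with a median of 0.71 and 2 members past 2-fold, Slc18a2 (1.87) and Srgn (1.21). That median was smaller than in wild type, where low values on the wild-type control array may have raised it. Megakaryocyte genes had a median of 1.33 (5 of 5 above 0, 3 past 2-fold), with Itga2b at 1.56 and Gfi1b at 1.51. The stem cell list stood at 0.52 (6 of 8 above 0), the granulocyte and monocyte list at 0.64 (8 of 8) and the glucocorticoid response list at 0.33 (8 of 10, with Txnip at 1.01). Here too most megakaryocyte, stem cell, granulocyte and monocyte genes on the array lay below the floor in both cultures. Besides Bcl6 and Slc18a2, the largest higher differences were Rpl3l, a muscle paralog of a ribosomal protein gene (2.65), Cd59a (2.55), the receptor accessory gene Ramp1 (2.40), Cited4 (1.96), Cyp2d22 (1.93) and Bmf, a proapoptotic BH3-only gene (1.83). The integrin gene Itgb4 was at least 6.02-fold higher, Phlda1 3.38-fold and the MAX dimerization gene Mxd4 3.18-fold. Of 6159 genes compared, 104 were at least 2-fold higher and 146 at least 2-fold lower, with 5 and 8 past 4-fold. Simulation from the spread alone gave a median of 69 genes, since the spread is wider here, and 135 of the 250 genes also exceeded 3 times their spread.

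Loss of Btg1 without ETV6-RUNX1, set against wild type with the same control virus, went with few differences. The sex of the embryos may differ between these cultures, so the Xist difference may not reflect the knockout. Among genes at or above the floor on both arrays, the largest lower values after Btg1 (-2.85) were Xist, the RNA of the inactive X chromosome (-1.99), Capsl (-1.30), Med25 (-1.23), Megf10 (-1.18), Rag1 (-1.18, spread 0.13), Trrap (-1.14) and Vapb (-1.13). Dnase1l3 and Mxd4 were lower by at least 4.09-fold and 2.02-fold, and Cdkn2a differed by -1.07. Among the genes with higher values were again those of mast cells and basophils, with 10 of 11 members above 0, a median of 0.61 above all random lists, and Fcer1a, the alpha chain of the IgE receptor, at 1.25. This comparison shares the wild-type control array with the ETV6-RUNX1 comparison in wild type, so low mast cell values on that array raise both. Adora3 (1.497), MGL1 (1.41), the Fc receptor gamma chain gene Fcer1g (1.33), Rnase12 (1.32), Cadm1 (1.29) and Slc2a6 (1.23) were also among the largest. Cacna1h, Rnase6 and Slc24a3 were at least 3.74-fold, 2.36-fold and 2.12-fold higher. Stem and early progenitor genes had a median of 0.49 (6 of 8 above 0) and MYC and ribosome biogenesis genes of 0.13 (12 of 14 above 0, percentile 99.8). Only 22 genes were at least 2-fold higher and 19 at least 2-fold lower of 6097 compared, against a median of 7 in simulation from the spread.

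With ETV6-RUNX1 present, loss of Btg1 went with lower ribosome biogenesis genes and higher B-cell genes. The MYC and ribosome biogenesis list had a median of -0.81 with 14 of 14 members below 0, and Srm differed by -1.61 (spread 0.28), Gnl3 by -1.38 and Rrp12 by -1.32. Besides Srm, the lowest differences after Btg1 (-2.002) were Gja1 (-1.97), Ifrd2 (-1.88), Cish (-1.78), Gldc (-1.70), Dctd (-1.59) and Grwd1, a ribosome assembly gene (-1.53). Ccdc42, the ribosome assembly gene Rpf2 and Serpina3g were lower by at least 3.04-fold, 2.89-fold and 2.62-fold. B-cell progenitor genes were above 0 in 20 of 21 members with a median of 0.46, above all random lists, and the B-lymphoid kinase gene Blk differed by 1.34 (spread 0.28). Rpl3l (2.07), Camk2b (1.79), Lgr5 (1.75), Ifi27 (1.71), Bcl6 (1.55, spread 0.41), Smtnl2 (1.41) and Mxd3 (1.39) had the largest higher values, and Ccl9 was at least 2.46-fold higher. Bmf differed by 1.12, and Cd74 by -1.04 while the other 4 measured dendritic cell and MHC class II genes lay above 0. Mast cell and basophil genes did not stand apart here, with a median of -0.06 and 7 of 11 below 0. In all, 41 genes were at least 2-fold higher and 56 at least 2-fold lower of 6106, against a median of 31 in simulation, and 58 of the 97 exceeded 3 times their spread. This comparison and the one of ETV6-RUNX1 in the knockout share the knockout array with ETV6-RUNX1, so values particular to that array enter both.

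Cells with both lesions were then set against the wild-type control. Among genes at or above the floor on both arrays, the 6 largest higher differences were Rpl3l (2.43), Tyrobp (2.21), Adora3 (2.21), Bcl6 (2.11), Fcer1g (2.01) and Ccnd1 (1.97), and the lowest were Gldc (-2.80), Cish (-2.37), Gja1 (-2.36), Gbp6 (-2.12), Ifrd2 (-2.05) and Syndig1l (-2.03). Mast cell and basophil genes had a median of 1.56 with 10 of 11 past 2-fold, megakaryocyte genes 1.30, B-cell progenitor genes 0.31 and MYC and ribosome biogenesis genes -0.84. The STAT5 list stood at -0.58 (percentile 0.03). In this comparison 161 genes were at least 2-fold higher and 110 at least 2-fold lower of 6173, against a median of 63.5 in simulation.

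The factorial design asks whether ETV6-RUNX1 acts alike in both genotypes, and without replicates only the size of the difference is given. The arrays gave no readout of the fusion transcript, so an unequal amount of it between the genotypes could not be checked. The effect was more positive in the knockout for Camk2b (2.60), Rpl3l (2.28), Vapb (2.25), Bmf (2.15), Tatdn2 (2.05) and Bcl6 (1.97), and more negative for Gja1 (-2.06), Ifrd2 (-1.98), Srm (-1.97), Dctd (-1.86) and Cd74 (-1.81). By list, the difference of effects was -0.95 for MYC and ribosome biogenesis genes (12 of 12 below 0) and -0.64 for mast cell and basophil genes (9 of 10 below 0). It was 0.57 for B-cell progenitor genes (19 of 19 above 0) and 0.67 for glucocorticoid response genes (6 of 8 above 0). The mast cell value came mainly from the control arrays. With Btg1 loss that list had a median of 0.61 without ETV6-RUNX1 and -0.06 with it. Low values on the wild-type control array may therefore account for it. Of 5442 genes at or above the floor on all arrays, 91 differed by at least 2-fold toward the knockout and 131 the other way, and 87 of these 222 exceeded 3 times their spread.

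Across those 5442 genes, which are not independent replicates, the ETV6-RUNX1 effects in both genotypes correlated at Pearson r = 0.296 and Spearman rho = 0.209, and 56.6% of genes had the same sign. These effects share no array. Both held 12 genes at least 2-fold higher, where independent lists of these sizes would share 1.05, and 6 at least 2-fold lower, where independent lists would share 0.277. Named genes of the first kind were Ccnd1, Neo1, Nfe2 and Tyrobp, and of the second kind Apbb1, Celsr1, Clic6 and Gldc. The effects of Btg1 loss with and without ETV6-RUNX1, which also share no array, correlated at r = -0.120 and rho = -0.157, with 43.9% of genes of the same sign.

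**Figure D3:**
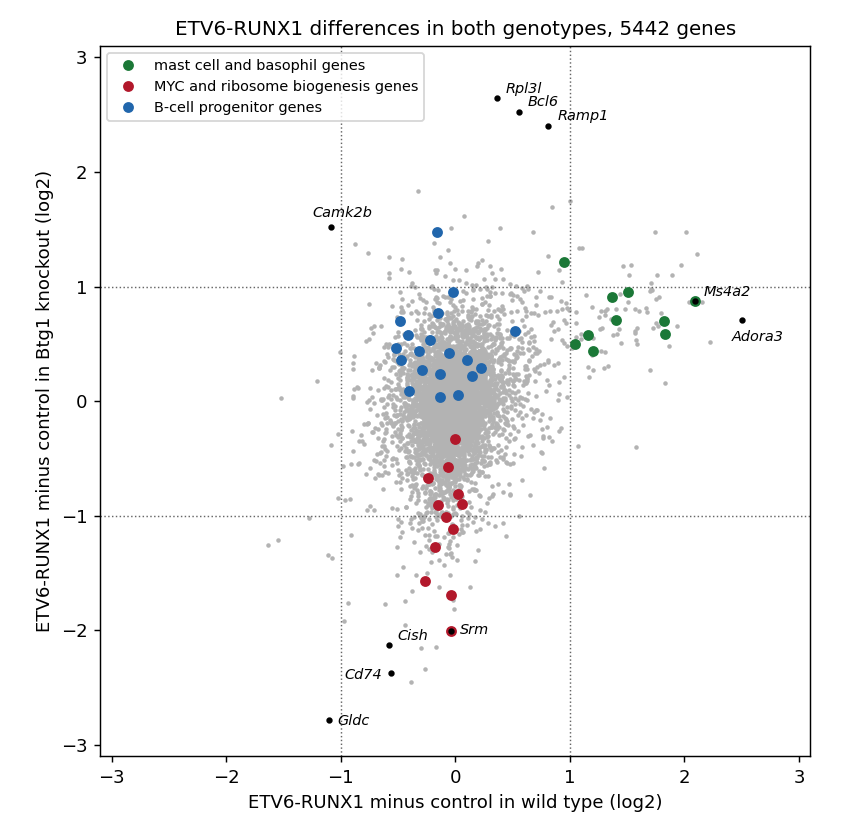
Log2 difference between ETV6-RUNX1 and control virus in wild type (horizontal axis) and in the Btg1 knockout (vertical axis) for 5442 genes, 1 gray point per gene, with dotted lines at 2-fold and 3 gene lists in color. Mast cell and basophil genes lie to the upper right, MYC and ribosome biogenesis genes at the bottom near 0 on the horizontal axis, and Bcl6 at 0.55 and 2.53.

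Other lists served as controls. Housekeeping genes had medians between -0.05 and 0.09 in the 5 comparisons, with Actb between 12.12 and 12.26 and Gapdh between 13.99 and 14.11. Single members varied more, though none passed 2-fold. With Btg1 loss Ywhaz differed by 0.76 without ETV6-RUNX1, and Gusb by -0.43 with it. Mitotic and S-phase genes had medians between -0.07 and 0.06, and none of their 24 measured members passed 2-fold. Of the hepatocyte and stromal genes 1 was measured, and of the erythroid genes 3 at most. Genes that BCL6 is known to repress were listed together with Bcl6. With ETV6-RUNX1 their median was -0.22 in wild type (7 of 12 below 0, percentile 0.35) and -0.004 in the knockout (6 of 12 below 0, percentile 46.6). With Btg1 loss it was 0.02 without ETV6-RUNX1 (percentile 65.1) and -0.27 with it (7 of 12 below 0, percentile 0.65). In the combined comparison it was -0.18 (6 of 12 below 0, percentile 7.8). These medians did not follow Bcl6, whose largest difference, 2.53, went with the median of -0.004. The sex-linked genes differed between genotypes. Xist stood at 8.996 and 8.59 in wild type without and with ETV6-RUNX1 and at 7.01 and 7.85 in the knockout. The Y-linked gene Eif2s3y stood at 9.43, 9.07, 9.93 and 10.03 in the same order, and Kdm5d was above the floor in the knockout alone, at 6.92 and 6.49.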

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

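With 1 array per group none of the differences below was tested. The tests of mast cell values on the wild-type control array, of mitotic genes and of genes that escape X inactivation were chosen after the results had been seen.

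Genes were singled out where the effect was at least 2-fold higher in one background and at least 2-fold lower in the other. Camk2b differed by -1.09 with ETV6-RUNX1 in wild type and by 1.52 in the knockout, a difference of 2.60. Its lower values, 6.04 in wild type with ETV6-RUNX1 and 6.32 in the knockout control, lay close to the floor. With Btg1 loss, Bmf differed by -1.04 without ETV6-RUNX1 and by 1.12 with it, a difference of 2.15. Vapb differed by -1.13 and 1.12 (difference 2.25). Mxd4 differed by -1.02 as a bound and by 1.05, a difference of at least 2.07, since its knockout control value lay below the floor. Among 5442 genes, opposite 2-fold effects of ETV6-RUNX1 were seen in 1 gene where independent lists would give 0.162 in that order, and in 0 where they would give 1.79 in the other order. For Btg1 loss, 2 genes were lower without ETV6-RUNX1 and higher with it, where independent lists would give 0.072, and 0 the other way, where they would give 0.161. No gene list met the same condition.

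The higher mast cell and basophil genes with ETV6-RUNX1 were weighed first. A low wild-type control array alone is argued against, because the effect in the knockout, which does not use that array, had a median of 0.71 with 11 of 11 genes above 0. A larger share of mast cells or basophils in the cultures with the fusion stays open: a second list of 12 mast cell genes, of which 6 were measured, had medians of 1.08 in wild type and 0.81 in the knockout, at or above the 99.99th percentile. Granulocyte and monocyte genes were higher as well, with medians of 0.70 in wild type and 0.64 in the knockout. The second list was not set against other myeloid cells, so it does not show a shift limited to mast cells. Higher expression within the same cells would give the same values, and the culture steps given above name no later sort that removed mast cells. For the higher mast cell genes with Btg1 loss without ETV6-RUNX1, a low wild-type control array may account for the values, since the same list had a median of -0.060 with Btg1 loss in the presence of ETV6-RUNX1, though an effect limited to cells without the fusion would look alike.

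The array of knockout cells with ETV6-RUNX1 combined low ribosome biogenesis genes with a wide spread of values, a robust standard deviation of 0.258 against the mean of the other arrays where the others had 0.121 to 0.162. Noise independent from gene to gene is argued against as the source of the low ribosome biogenesis genes. In a second ribosome biogenesis list of genes not looked at before, 100% of the 15 measured members were lower than in the knockout control, with a median of -1.01. That list cannot tell whether such noise adds to the wide spread over all genes, which stays open. Fewer dividing cells, to the extent of the ribosome biogenesis shift, are argued against by the mitotic and S-phase genes. Their median was 0.043 where the ribosome biogenesis list stood at -0.96. Of these genes 13 lay above 0 and 10 below, from -0.50 for Ccne1 to 0.55 for Kif11. A slower entry into the cell cycle is not covered by that median. Ccnd2 (-1.01) and the CDK inhibitor gene Cdkn2d (0.91) went one way and Ccnd1 (1.19) the other. RNA quality stays open, since genomic gene length, a weak stand-in for transcript length, gave a Spearman rho of 0.09 across genes (0.0854) and could not exclude it. That rho was not particular to this array. It was 0.03 for the wild-type control, -0.12 for wild type with ETV6-RUNX1 and -0.06 for the knockout control. An effect of both lesions together and a difference in the state of this 1 culture at harvest cannot be told apart without a second culture, and the biological explanation was not tested.

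Xist was lower and Y-linked genes were higher in the knockout cultures. Whether the knockout pools held a larger share of male embryos stays open. Xist, the measured Y-linked genes and the genes tested next all lay on the side that it would give. Embryo sex may thus differ along with genotype in every comparison of Btg1 loss. Sex-linked differences there cannot be assigned to the knockout. The test used genes that escape X inactivation, of which 3 of 4 were measured and all 3 were below 0 with Btg1 loss. Their medians were -0.186 without and -0.445 with ETV6-RUNX1, at the 4.09th and 2.30th percentiles of random lists, and only the latter passed the bound of 2.5. The labels give no sex of the embryos, and no biological explanation was tested.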

How the results depend on the processing

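All alternatives named here except the scaling and the restriction to genes above the floor on all 4 arrays were chosen after the data were seen. Both planned ones left every total of genes past 2-fold within 1.5 times, every correlation in sign and size, and Btg1 and Bcl6 within their spread. Much of this was fixed in advance. The correlations and the difference of effects were already taken over genes above the floor on all 4 arrays. The restriction therefore repeats them, along with the values of the single genes that it keeps. The scaling acted on arrays that RMA had already made alike. Of the separate counts of higher and lower genes, 2 moved further under the restriction: genes lower with ETV6-RUNX1 in wild type from 22 to 13, and genes higher with it in the knockout from 104 to 68. The restriction also moved 18 list medians and left 126 within the spread of random lists. No called value changed sign under any alternative that was run. For single genes a change of floor cannot reverse a sign, so only the scaling could have done so. Over all alternatives, of the list medians 618 values stayed within the spread of random lists and 115 moved beyond it, and of the named genes 2794 stayed within their spread and 240 moved. Of the named gene values that stayed, 651 came from the scaling and 506 from the restriction, under which none moved. The counts depended on the floor. Genes past 2-fold numbered as follows with floors of 5 and 7 and with none. ETV6-RUNX1 in wild type gave 241, 75 and 1574, and in the knockout 379, 152 and 1690. Btg1 loss gave 100, 19 and 1468 without ETV6-RUNX1, and 174, 50 and 1404 with it. The combined comparison gave 431, 166 and 1824, and the difference of effects 374, 121 and 3217. Most genes lie below the floor, so a count without a floor is taken over many more genes, and no simulated count was made for it. Requiring 3 times the spread gave 135 genes for ETV6-RUNX1 in the knockout, 58 for Btg1 loss with ETV6-RUNX1, 177 for the combined comparison and 87 for the difference of effects, fewer since a second condition is added. Without a floor the correlations were 0.11 between ETV6-RUNX1 effects and -0.0028 between Btg1 loss effects. Bcl6 with ETV6-RUNX1 in the knockout was 1.86 with a floor of 7, which lies above its control value.

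Background corrections, normexp offsets, detection p-values and the mean of all probes were planned and not run, since the raw signal columns match no sample's labels. Leaving out the array of knockout cells with ETV6-RUNX1 removes the comparisons that use it. A paired analysis, with the 2 backgrounds as pairs for each factor, would leave 1 residual degree of freedom and was not run. Signal over background limits what can be said of genes below the floor, since only 32.4% to 32.6% of genes per array lay at or above it.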

Other observations

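The ribosomal protein genes, the second ribosome biogenesis list and the interleukin 7 list below were all chosen after the fixed lists had been seen, and the interleukin 7 list after Bcl6, Rag1, Bmf and Cish had been seen. The median of the ribosomal protein genes did not follow that of the ribosome biogenesis genes. The 49 measured cytosolic ribosomal protein genes had a median of 0.00 with ETV6-RUNX1 in the knockout (23 above 0, 24 below), where the second ribosome biogenesis list had -1.01 with 8 of 15 members at least 2-fold lower. Members of the ribosomal protein list ranged from -1.06 to 0.36. Many of them stood near the highest level of the arrays, 14.91 to 14.92, where a difference may not show. Their median therefore cannot exclude lower levels. In the second ribosome biogenesis list Rcl1 differed by -1.34 and Bop1 by -1.25. Mybbp1a, Rrp1b and the polymerase I subunit gene Polr1a lay below the floor with the fusion and differed by at least 1.61, 1.60 and 1.03 toward lower values. With ETV6-RUNX1 in wild type the same list had a median of -0.21 (13 of 16 below 0), and with Btg1 loss without ETV6-RUNX1 it had 0.05. The members of that list were fixed without looking at their own values.

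Lists with smaller differences complete the account of the knockout cells with ETV6-RUNX1. Against the knockout control, CDK inhibitors and D cyclins had a median of 0.35 (6 of 9 above 0, percentile 98.9), RUNX1 target genes 0.43 (6 of 7 above 0, percentile 99.6), TGF-beta response genes 0.35 (5 of 8 above 0) and p53 target genes 0.15 (10 of 15 above 0). Apoptosis regulators had 0.17 (9 of 12 above 0), interferon response genes 0.10, hypoxia and glycolysis genes -0.06 and T and NK cell genes -0.23. Of the genes high in human leukemia with ETV6-RUNX1, Rag1 and Rag2 were measured. Rag1 differed by 1.47, and Rag2, below the floor in the knockout control, by at least 0.64.

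Against the knockout control, higher Bcl6, Rag1, Bmf and Mxd4 with lower Cish resembles what pre-B cells show when interleukin 7 signaling weakens and FOXO factors act. Part of this rests on low values in that control, since against the wild-type control Rag1 differed by 0.297 and Bmf by 0.79, and against wild type with ETV6-RUNX1 Rag1 differed by 0.455. As a hypothesis, this culture may have had weaker interleukin 7 or stronger FOXO signaling at harvest. A list of 22 genes that leaves out Bcl6, Rag1, Bmf and Cish had medians of 0.44 against the knockout control (16 of 18 above 0) and 0.46 against wild type with ETV6-RUNX1 (17 of 18 above 0). Many of its members, such as Rag2, Il7r, Irf4, Spib, Blnk, Foxo1 and Cd22, are also in fixed lists whose values had been seen, so these medians partly restate the B-cell result. The test therefore used the 10 members that are in no fixed list, 7 of them measured. Their medians were 0.454 against the knockout control (6 of 7 above 0, percentile 99.5) and 0.336 against wild type with ETV6-RUNX1 (7 of 7 above 0, percentile 99.6). In wild type ETV6-RUNX1 gave them a median of -0.14, and Btg1 loss without the fusion -0.15. The fixed STAT5 target list went both ways. Against the knockout control Cish, Bcl2 and Ccnd2 were at least 2-fold lower and no member was 2-fold higher, with a median of -0.12 (5 of 9 below 0), and against the wild-type control the median was -0.58 (percentile 0.03). Against wild type with ETV6-RUNX1 the median was 0.024 (5 of 9 above 0, percentile 58.3), and Il2ra, a STAT5 target in both lists, was higher by at least 0.44. The hypothesis stays open. More B-lineage RNA in this culture is not excluded, the comparisons that show the shift all use the same array, and a second culture would be needed to tell an effect of the lesions from the state of that culture.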
